A study of Halobacterium salinarum NRC-1 with 8 samples.

How the data were processed

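The study measured total RNA of 4 cultures of an NRC-1 strain lacking ura3 and zim on 8 dual-channel spotted arrays. Replicate 1 of each culture was labelled with Alexa 532 and replicate 2 with Alexa 647, and the other channel held RNA of the standard NRC-1 reference, per the labels. The 2 arrays of a culture are a dye swap of the same comparison and were treated as 1 replicate. Each condition thus has 1 culture, and the p-values of the 3 main comparisons rest on 1 residual degree of freedom among 4 cultures, with the spread pooled over genes. Alternatives that drop terms, leave out cultures or fit the 8 arrays have other degrees of freedom. The pooled spread is estimated anew in each alternative, so a smaller p there is not by itself stronger evidence.

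Per the file headers, the scanner files hold spot and local background intensity for each dye, as means, medians and SDs, at 2 scanner settings, with no normalization. They also hold a deposited spot confidence score from 0 to 100; every spot below the top score had a pixel at the scanner ceiling of 65535, so the score marks saturation and no quality flag was found. A further deposited table holds the authors' processed values. Compared with the scanner intensities, the authors' values are log10 ratios of Alexa 532 over Alexa 647 on every array, with dyes not turned. Their order follows the whole slide and was matched to the scanner order, after which they correlated with the scanner ratios at r = 0.787, 0.591, 0.878, 0.907, 0.457, 0.370, 0.627 and 0.981, for replicates 1 and 2 of high oxygen in light, high oxygen in the dark, low oxygen in light and low oxygen in the dark. The medians of its columns, in the same order, were 0.0761, 0.0423, 0.0830, 0.122, 0.0283, 0, 0 and 0.0483, and how they were centred stays unknown. On 7 of the arrays 164 spots have no value in it. This table served as an alternative only. The image software and the authors' normalization are not given in the sources used here.

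Each array has 10752 spots in 48 print blocks, with 2688 probe positions of 4 spots each. A table of the array's annotation pairs 532 spots with 133 genes, 4 spots per gene, with 0 genes under several names; the other 2555 positions are unnamed here and are given by probe ID. All 133 symbols were found in the annotation table of Halobacterium salinarum strain 91-R6, a different strain, which was used only for names and for which genes are neighbours; no coordinates are given.

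Intensities were processed in R 4.3.3 with limma 3.58.1 and statmod 1.5.0. The high-gain scan was used, with median foreground and median background, normexp background correction with offset 50, and loess within each array over all spots. No scaling was applied between arrays. The log2 ratios were turned to culture over reference, the 4 spots of a position were averaged, and the 2 arrays of a culture were averaged. A position counted as above background on an array where mean foreground exceeded mean local background by 2 background SDs in either channel, and as measured where this held on at least 4 arrays. All positions entered the tests. Bounds against a culture whose channel was below background on both arrays set the brighter culture's mean against the higher of the lowest signal above background and the gene's own signal, per channel after loess and Aquantile, and each rests on a balanced dye swap. Such a bound is of channel signal and can take in the staining of the arrays.

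The model had terms for oxygen, light and the mean against the reference, fitted with lmFit and eBayes (prior degrees of freedom 7.80), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The reference was the same RNA on all arrays, so its own spread is left out. The oxygen by light difference takes the residual degree of freedom and has no test across cultures; a fit of the 8 arrays with a dye term covers hybridisation error only. Gene lists were tested with camera, preset correlation 0.01, on the 132 named genes other than pyrF, with an estimated correlation beside it. With 1 residual degree of freedom that estimate rests only on the signs of the members' oxygen by light values. It came out as 0.333 for the purine and 1 for the pyrimidine list. Adjusted p under it, also where it ends a range below, is therefore no check of the list calls. With the preset correlation the members of a list count as nearly independent. The tested pyrimidine genes are pairs of neighbours in the annotation strain, carB with carA and pyrB with pyrI. Calls of that list may thus rest on fewer than 4 independent values. Of 29 lists, 6 had at least 4 measured members and were tested: chemotaxis and transducers, citric acid cycle, cobalamin synthesis, phototrophy, purine synthesis and pyrimidine synthesis. For 10 lists only values are given, and 13 hold no named gene here. Percentiles of list medians come from 10000 random lists of equal size.

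The design, the lists, the settings above and the alternatives called planned were fixed before the data were examined, as was the rule for named genes. For each comparison it takes up to 10 named genes past the threshold in each direction. Places left are filled, as values, by the largest differences among measured genes with 1 sign in every separate comparison: in light and dark or high and low oxygen and both dye orientations, or on all 8 arrays for the reference. It takes 5 in each direction for the oxygen by light difference, up to 4 members of each list, and always pyrF, bat, arcA and arcC among the genes named here. Applied to unnamed probes it is limited here to 2 measured calls in each direction.

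The pipeline was tested on simulated data with 200 of 2688 positions changed. At a log2 size of 0.5 it recovered 95.5% for the reference, 12.5% for the oxygen and 0% for the light comparison. At a log2 size of 1 it recovered 100%, 89% and 98%, and at 2 it recovered 100% in each. Unchanged positions called in the same order of comparisons numbered 15, 8 and 0 at the size of 0.5, 4, 16 and 29 at 1, and 4, 18 and 8 at 2. A purine list shifted by 1 log2 was recovered in 100 of 100 simulations. Contrasts left unshifted had a camera p under 0.05 in 4%. No smaller list shift was simulated, and the list medians called below reach at most 0.43, so recovery at their sizes is not known. The number of arrays and cultures limits the precision of every value. Alternatives covered the background correction, the normalization within and between arrays, filters on dim positions, the authors' values, the variance model, the covariates, the unit of replication, each dye orientation, and leaving out each array and each culture. With a culture left out, the oxygen or light fit keeps only the tested factor and the reference fit no factor, since 3 cultures leave no residual degree of freedom otherwise. Added after the data were seen were the spot statistic, the low-gain scan, leaving out saturated spots, and further settings for lists and pyrF, among them the lists without covariates. The low-gain scan was run with mean foreground and mean background, so it changes the spot statistic as well as the gain. Spots left out as saturated had a confidence score under 50 in either dye, 4.25% of all spot values. Spots scored from 50 to below the top score, which also had a pixel at the ceiling, stayed in.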

Results

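RNA was measured from 4 cultures of Halobacterium salinarum NRC-1, a salt-loving archaeon that can respire oxygen, ferment arginine and use light energy through retinal proteins. The strain lacked ura3, also called pyrF, the gene for the last enzyme of UMP synthesis, and it lacked zim. Each culture stood for 1 combination of oxygen and light, and all were grown in rich medium to mid-log phase. High oxygen meant 50 mL shaken at 210 rpm in a 125 mL flask, and low oxygen meant 100 rpm in a stoppered flask. Each culture was hybridised on 2 spotted arrays with the dyes swapped, against RNA of a standard NRC-1 reference culture in mid-log phase. The arrays therefore number 8, but each condition has 1 culture and so no biological replicate. All log2 values below are culture over reference, with the dye-swapped pair averaged.

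Of 2688 probe positions, 981 were above background on at least 4 of the 8 arrays, 248 on all 8 and 1128 on none. The names used here cover 133 genes, of which 82 were above background on at least 4 arrays; these are called measured below. The arrays differed in quality. Replicates 1 and 2 had 958 and 760 positions above background for high oxygen in light, 1268 and 1469 for high oxygen in the dark, 1160 and 861 for low oxygen in light, and 468 and 266 for low oxygen in the dark. On the last of these the median spot signal was 0.967 times the local background in the Alexa 532 channel and 1.01 times in the Alexa 647 channel. The SD of log2 ratios over measured positions was 0.597 and 0.445 on the low oxygen dark arrays, against 0.225 to 0.248 on the other 6. In that culture's own channel, 51 of the 82 measured named genes were below background on both arrays, so their values below that draw on this culture are not measured levels there.

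**Figure D1:**
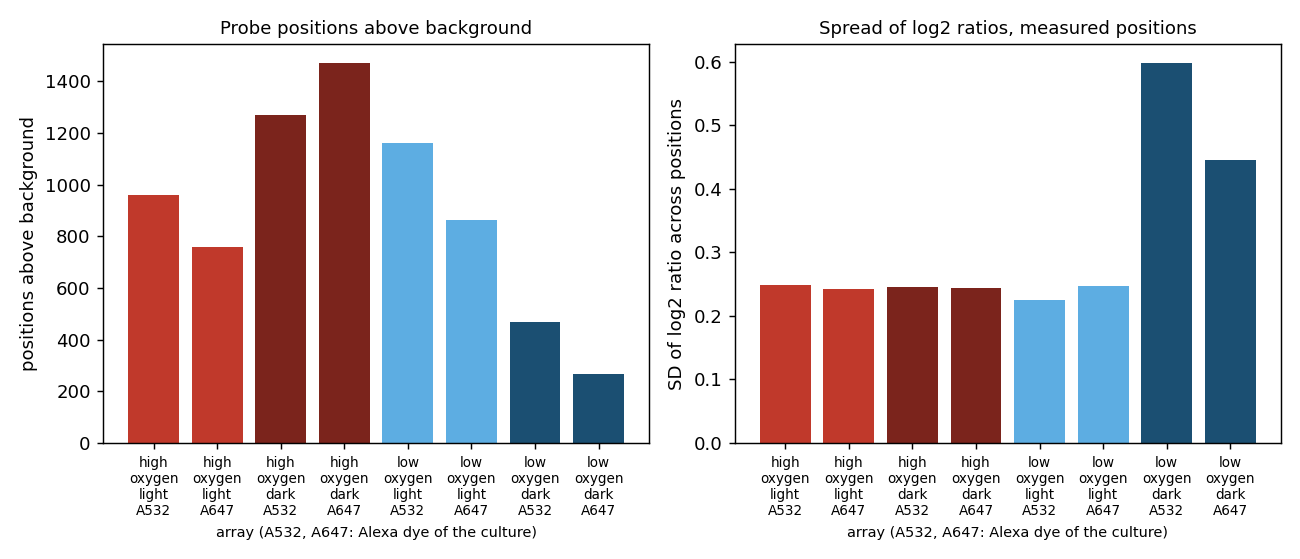
Probe positions above background (left, count) and SD of log2 ratios over the 981 measured positions (right, log2 units) on each of the 8 arrays, labelled by condition and by the Alexa dye of the culture. The low oxygen dark arrays have 468 and 266 positions above background and SDs of 0.597 and 0.445.

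The comparison of all 4 cultures with the reference asks how the deletion strain, over these conditions, differed from standard NRC-1 RNA. The deleted gene pyrF read lower than the reference on 8 of 8 arrays, with a mean log2 ratio of −0.86 (SE 0.0971, n = 4 cultures, limma adjusted p = 0.00417). Its probe was not above background in either channel on any array, so no fold is given. Whether the probe lies within the deleted part is not given in the sources used here. The authors' values, whose centring is unknown, gave −0.37 and were lower on 4 of 8 arrays, those with the culture in Alexa 647, or −0.36 and 6 of 8 with each array centred on its median. No background subtraction gave −0.47 and mean foreground and background −0.55. The low-gain scan, which also changes the spot statistic to mean foreground and background, gave −0.0727 (limma adjusted p = 0.540). Over all alternatives adjusted p ranged from 7.6e-10 to 0.540. The call was lost with scaling between arrays (−0.86) and in the Alexa 647 orientation (−0.94). It was also lost without the high oxygen light (−0.87), high oxygen dark (−0.89), low oxygen light (−0.92) or low oxygen dark culture (−0.78), in fits that also drop the oxygen and light terms. Values for zim were not analysed here. Among the other named genes phoU, a regulator of phosphate uptake, had a log2 ratio of −0.58 (SE 0.0908, limma adjusted p = 0.0171), and was lower on 8 of 8 arrays. In the low oxygen dark culture's channel phoU was below background on both arrays, so no fold is given for it. Its call was lost with scaling between arrays (adjusted p = 0.121), in the Alexa 647 orientation (−0.37, adjusted p = 0.238), with mean foreground and median background (−0.54, adjusted p = 0.123) and with the oxygen and light terms dropped (adjusted p = 0.0692). With those terms dropped it was lost too without the high oxygen light (−0.65), high oxygen dark (−0.63), low oxygen light (−0.56) or low oxygen dark culture (−0.48). The full fit lost it without high oxygen dark replicate 1 (−0.52), and its adjusted p ranged from 1.4e-08 to 0.324 over the alternatives. These were the only 2 named genes past the threshold, and the same number passed when adjusted over the list alone.

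Other named genes lay below the reference on all 8 arrays without passing the test over all 2688 positions. They include glyA (−0.44), which interconverts serine and glycine, argH (−0.32), the last enzyme of arginine synthesis, pheA (−0.31), a phenylalanine synthesis enzyme, glnA (−0.21), glutamine synthetase, and asd (−0.18), an enzyme shared by lysine, methionine and threonine synthesis. The alanyl-tRNA synthetase gene alaS had −0.25. The gene listed as panB had −0.42; this name has been used for a pantothenate synthesis gene and for a proteasome regulator, and the sources used here do not settle which is meant. Their limma adjusted p ranged from 0.0768 for panB to 0.316 for asd. Some passed under alternatives, glyA in 8 of 30 (adjusted p from 2.5e-06 to 0.356 over all of them), panB in 8 of 29 (0.000118 to 0.446), argH in 4 (0.00412 to 0.546), pheA in 4 (0.00702 to 0.467), glnA in 2 (0.00135 to 0.667) and alaS in 1 (0.0356 to 0.585). Limiting the fit to measured positions gained 5 of these 6 genes, all but glnA, and the low-gain scan gained 5, all but alaS, with panB there at −0.23. Without the low oxygen dark culture and the oxygen and light terms, glyA had −0.29, argH −0.17, pheA −0.20 and glnA −0.14, and argH had −0.21 without only its replicate 1. In that culture's channel argH, pheA, asd, alaS and panB were below background on both arrays. No measured named gene lay above the reference on all 8 arrays. In all, 8 measured named genes kept 1 sign on all 8 arrays, 8 lower and 0 higher. The arrays share 1 reference and come in pairs from 4 cultures, so no chance share is given. The 132 named genes other than pyrF, measured or not, had a median of −0.071, against 0.0065 over the 981 measured positions. The named set had the lower median, but the sets also differ in the background filter. How far the naming itself matters is therefore not settled.

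Over all positions, limma called 30 higher and 34 lower than the reference, 64 in total, and 31 of these were positions not measured by the background criterion. At an unadjusted p under 0.05 there were 491, against 134.4 expected by chance. The unnamed probes 3451 (1.39, SE 0.115, adjusted p = 0.000764) and 1911 (0.98, SE 0.0938, adjusted p = 0.00204) lay highest among the measured calls. Probes 4433 (−1.88, SE 0.0939, adjusted p = 3.2e-05) and 4055 (−1.22, SE 0.127, adjusted p = 0.00322) lay lowest. The pyrimidine synthesis list rose with a median of 0.12 and 3 of 4 members higher, led by carB (0.27), a subunit of carbamoyl phosphate synthase (camera adjusted p = 0.0490, and adjusted p = 0.971 with an estimated correlation). No member of it passed the threshold over all genes or adjusted over the list alone, and carA and carB were above background in neither channel on the low oxygen dark arrays. The list call held with median centring (0.15), without high oxygen dark replicate 1 (0.13), low oxygen light replicate 1 (0.12), or any culture but low oxygen dark (0.13 to 0.18). It was lost without each of the other 6 arrays, without the low oxygen dark culture (0.034), and under every other setting in which lists were tested, among them the low-gain scan (0.052), the authors' values (0.045) and the test of measured positions alone (adjusted p = 0.0594). With the oxygen and light terms dropped, limma called 14 positions over the 4 cultures. In that form it called 0 without the low oxygen dark culture (433 at an unadjusted p under 0.05), and 2, 2 and 1 without the high oxygen light, high oxygen dark or low oxygen light culture. Leaving out a single array gave 16 calls without high oxygen dark replicate 1, 183 without its replicate 2, 158 without low oxygen light replicate 1 and 21 without low oxygen dark replicate 2; strain and growth condition are not separated in this comparison.

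The oxygen comparison asks which transcripts differ between well-aerated and oxygen-limited cultures, across light and dark. The purine synthesis list was called higher in high oxygen as a group, and no single gene passed. The largest value was that of purF, the entry enzyme of the pathway, at 0.69 (SE 0.250), followed by purL at 0.55, purM at 0.38 and purD at 0.37. The list of 6 purine genes had a median of 0.38 with 5 of 6 above 0, the other being purB, which was above background on no array (camera adjusted p = 0.0351, and adjusted p = 0.827 with an estimated correlation). The pyrimidine synthesis list was called lower, with a median of −0.18 and 4 of 4 members below 0 (camera adjusted p = 0.0351, and adjusted p = 0.827 with an estimated correlation). The members are pairs of neighbouring genes, so 4 of 4 may stand for fewer independent values. Their lowest values were −0.42 for carB, which the low-gain scan turned to 0.22, and −0.26 for pyrI, the regulatory chain of aspartate carbamoyltransferase, which the authors' values turned to 0.017. On the low oxygen dark arrays carA and carB were above background in neither channel, so no fold is given for them, while pyrB (−0.097) and pyrI were above background on all 8 arrays.

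Most of this difference lay between the dark cultures. The purine list's high minus low oxygen median was 0.62 in the dark and 0.14 in light, where 6 of 6 genes were higher. In purF the oxygen difference was 1.21 in the dark and 0.17 in light, and in purL 1.06 and 0.042. The 5 measured purine genes were above background in the culture channel on 6 arrays and on neither low oxygen dark array, so against that culture only a bound holds. High oxygen in the dark exceeded it at least 1.11-fold for purF, 1.28-fold for purL, 1.30-fold for purD and 1.13-fold for purE, and no bound above 1 could be had for purM. In these 5 genes the reference channel was also below background on both arrays. The bounds therefore hold for the signal of the culture's channel, array staining included, not for its ratio to the reference. Fits without a culture also drop the light term, without which the 4 cultures together kept both calls. Without the low oxygen dark culture purF had 0.062 and purL 0.035, the purine median was 0.065 (adjusted p = 0.379) and the pyrimidine median −0.014 (adjusted p = 0.664). The purine call was also lost without the high oxygen light culture (0.37), high oxygen light replicate 1 (0.35), high oxygen dark replicate 1 (0.35), low oxygen light replicate 1 (0.41) or low oxygen dark replicate 1 (0.27). The pyrimidine call held without high oxygen dark replicate 2 (−0.24) or the low oxygen light culture (−0.34) and was lost without any other array or culture, the median being −0.094 without low oxygen dark replicate 1, and the authors' values turned it to 0.00033. Among the settings, the purine call was lost with offset 0 (0.38), median centring (0.53), scaling between arrays (0.32), the authors' values (0.31), the Alexa 647 orientation (0.22) and saturated spots left out (0.38), and the low-gain scan lowered its median to 0.20. Leaving out the low oxygen light culture kept it at 0.63. The pyrimidine call held under 3 settings, no background subtraction (−0.11), measured positions alone (−0.18) and the Alexa 532 orientation (−0.30), and with the light term dropped. Over the alternatives the adjusted p ranged from 0.000114 to 0.827 for the purine and from 0.00469 to 0.827 for the pyrimidine list.

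**Figure D2:**
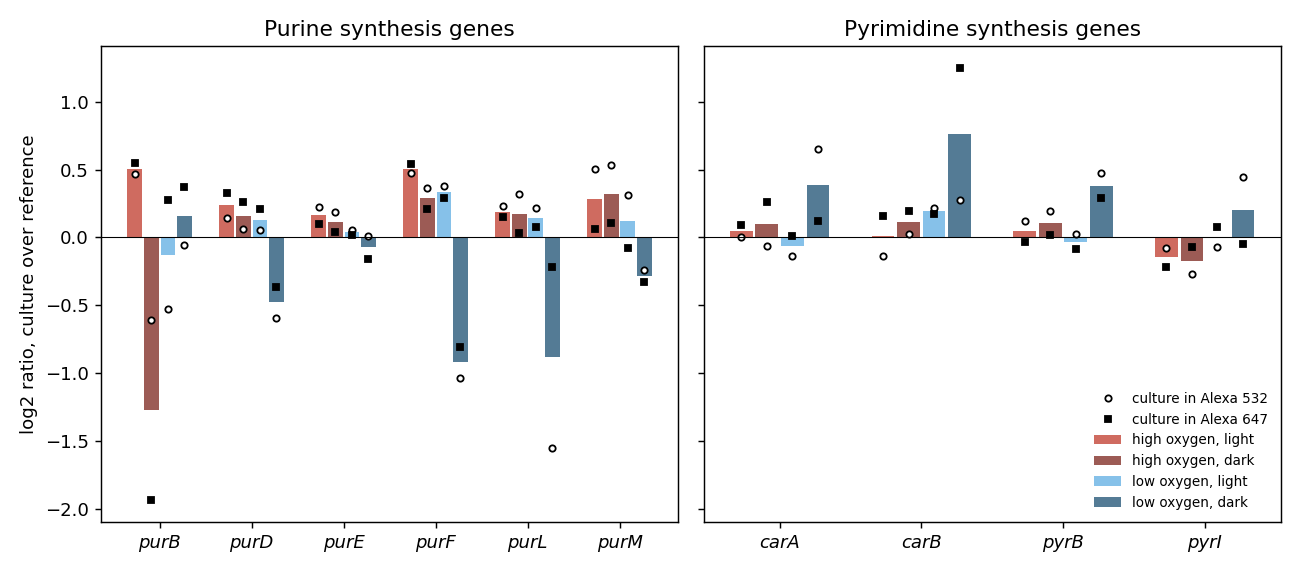
Log2 ratio of culture over reference for the purine and pyrimidine synthesis genes other than pyrF; bars are the mean of the dye-swapped arrays of 1 culture, and points are the single arrays by the culture's dye. In the low oxygen dark culture purF has −0.92 and purL −0.88, while carB has 0.76. There the purine genes, carA and carB were above background on neither array, and purB was not above background on any array.

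No single gene passed the oxygen test over all 2688 positions: limma called 0, the lowest adjusted p was 0.973, and 128 positions had an unadjusted p under 0.05, 35 higher and 93 lower. None of the named genes passed when adjusted over the list alone. Besides the purine genes, the values highest in high oxygen with 1 sign in every separate comparison were sucD (0.42), a subunit of succinyl-CoA synthetase, sop1 (0.42), the phototaxis receptor sensory rhodopsin I, moaC (0.35), a molybdenum cofactor synthesis gene, phoU (0.35), lpdA (0.31), dihydrolipoamide dehydrogenase, and cheA (0.31), the chemotaxis histidine kinase. The lowest besides carB and pyrI was thrS (−0.20), the threonyl-tRNA synthetase gene. All 7 values were closer to 0 without the low oxygen dark culture, in whose channel sop1, moaC, phoU, cheA and thrS were below background on both arrays. Without it and the light term sucD had 0.053, sop1 0.16, moaC 0.14, phoU 0.23, lpdA 0.14, cheA 0.14 and thrS −0.038. Over all arrays and cultures left out in turn, sucD ran from 0.053 to 0.79, sop1 from 0.16 to 0.67, moaC from 0.097 to 0.61, phoU from 0.19 to 0.51, lpdA from 0.14 to 0.49, cheA from 0.14 to 0.48 and thrS from −0.36 to −0.038. The gene of the other succinyl-CoA synthetase subunit, sucC, had an oxygen difference of 0.023 over all 4 cultures, against 0.42 for sucD. Of the 82 measured named genes 21 kept 1 sign in light and dark and in both dye orientations, 18 higher and 3 lower, against 14.3 expected if the difference in light and that in the dark were unrelated, from the 45 and 46 genes that kept a sign in both orientations within each. When the fit was limited to the 981 measured positions, limma called 17 positions, 1 higher and 16 lower, and the higher one was purF (adjusted p = 0.0177; over the alternatives for purF this ranged to 0.9996). Limiting it to positions above background on all 8 arrays gave 4. Leaving out high oxygen dark replicate 2 or low oxygen light replicate 1 gave 8 and 3 calls, and leaving out the high oxygen light culture together with the light term gave 5.

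Chemotaxis genes and transducers had a median of 0.21 in high over low oxygen, with 8 of 11 higher, and did not pass (camera adjusted p = 0.0504). The median was 0.32 in the dark, where the low oxygen dark culture enters, and 0.10 in light. The measured members with the largest values were cheA (0.31), cheB (0.29), the receptor methylesterase, cheY (0.28), the response regulator that acts on the flagellar motor, and the transducer gene htr6 (0.27). In the culture channel of the low oxygen dark arrays cheA, cheB and htr6 were below background on both and cheY on 1, so the order of these values is not settled. Against that culture, the cheA signal of high oxygen in the dark was at least 1.30-fold higher. No bound above 1 was had for htr6, and none is given for cheB, whose signals gave more than the 1.35-fold difference of its ratios. The cheA bound comes from the same calculation and is of signal only, array staining included. The phototrophy list had a median of 0.11 (adjusted p = 0.611), with 0.21 for htr1, the transducer of sensory rhodopsin I, and −0.070 for htr2, that of sensory rhodopsin II. For bat, the activator of bacteriorhodopsin synthesis, no array was above background. The citric acid cycle list had a median of −0.074, a mean of 0.031 and a camera direction of lower (adjusted p = 0.827), with mdh at −0.12 and citZ at −0.10. The cobalamin list likewise had a median of −0.033, a mean of 0.0053 and a direction of lower (adjusted p = 0.827). The arginine fermentation genes arcA (−0.14), arginine deiminase, and arcC (−0.10), carbamate kinase, had no value past the threshold, and arcC turned sign in 4 of 29 alternatives. With arrays and cultures left out in turn, arcA ran from −0.27 to −0.0047.

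Lists with fewer than 4 measured genes gave values only. Their median high minus low oxygen differences were 0.35 for phosphate uptake (phoU alone), 0.25 for haem synthesis, 0.19 for oxidative stress, 0.14 for carotenoid and isoprenoid synthesis (mvk alone), and 0.059 for both the chaperones and the proteasome, whose 4 members include panB. Electron transport had 0.055, ribosomal proteins 0.051 (rpl12p alone), arginine fermentation −0.12, and DNA repair −0.14, the last with 0 of 3 genes measured.

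The light comparison asks which transcripts differ between illuminated and darkened flasks, across both oxygen levels. The purine synthesis list was called higher in light as a group, and no single gene passed. The gene purF had 0.74 (SE 0.250), purL 0.52 and purD 0.34, and the list had a median of 0.43 with 6 of 6 above 0 (camera adjusted p = 0.0278, and adjusted p = 0.786 with an estimated correlation). One of them is purB, and the measured members alone had a median of 0.34. The pyrimidine synthesis list was called lower in light, with a median of −0.24 and 4 of 4 members below 0 (camera adjusted p = 0.0343, and adjusted p = 0.786 with an estimated correlation). Here too, neighbouring pairs may make 4 of 4 fewer independent values. The members were carB at −0.33, which the low-gain scan turned to 0.11, carA, the other subunit of carbamoyl phosphate synthase, at −0.25, pyrB, the catalytic chain of aspartate carbamoyltransferase, at −0.24 and pyrI at −0.087. Of these, carA and carB were above background in neither channel on the low oxygen dark arrays, so no fold is given for them.

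As for oxygen, the low oxygen dark culture carried most of both list differences. The purine light difference had a median of 0.51 in low oxygen and 0.064 in high oxygen, and the pyrimidine difference −0.43 and −0.057. In low oxygen, the signal in light exceeded that in the dark at least 1.09-fold for purF, 1.43-fold for purL and 1.05-fold for purE. No bound above 1 was had for purM. None is given for purD, whose signals gave more than the 1.53-fold difference of its ratios. Signal and ratio thus disagree for purD. The bounds of the other genes come from the same calculation and hold for signal only, array staining included. Fits without a culture also drop the oxygen term, without which the 4 cultures together kept both calls. Without the low oxygen dark culture the medians were 0.0082 (adjusted p = 0.198) and −0.054 (adjusted p = 0.933). The purine call was also lost without the high oxygen light culture (0.36) or high oxygen dark replicate 1 (0.44), and the pyrimidine call held without high oxygen dark replicate 1 (−0.26), low oxygen light replicate 2 (−0.25) or the high oxygen dark culture (−0.38) and without no other array or culture. The purine median was 0.25 without low oxygen dark replicate 1 and 0.13 with the low-gain scan, both still called. Its call was lost with the authors' values (0.24), in the Alexa 532 (0.33) and Alexa 647 orientation (0.26) and with saturated spots left out (0.43). The pyrimidine call was lost in these 4 settings (−0.16, −0.21, −0.18 and −0.29), with offset 0 (−0.24), with scaling between arrays (−0.18), with mean foreground and median background (−0.17), and without low oxygen dark replicate 1 (−0.15). Mean foreground and background kept it at −0.13, and no background subtraction at −0.16. Over the alternatives the adjusted p ranged from 4.9e-05 to 0.786 for the purine and from 0.0115 to 0.933 for the pyrimidine list.

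No single gene passed the light test: limma called 0 of 2688 positions, the lowest adjusted p was 0.511, and 237 had an unadjusted p under 0.05, 163 higher and 74 lower. None of the named genes passed when adjusted over the list alone. The highest values in light with 1 sign in every separate comparison, after purF, were sucD (0.52), purD, lpdA (0.29), cheB (0.28), dpsA (0.22), a ferritin-like protein that protects DNA, glnA (0.16), nuoL (0.14), an NADH dehydrogenase-like subunit, psmA (0.14), a proteasome subunit, which turned to −0.059 with saturated spots left out, and ppsA (0.13), phosphoenolpyruvate synthase. The lowest, after carB, were the aminoacyl-tRNA synthetase genes thrS (−0.25) and aspS (−0.25), pyrB, gyrA (−0.23), a DNA gyrase subunit, map (−0.21), methionine aminopeptidase, and infB (−0.17), a translation initiation factor. All of these but nuoL were closer to 0 without the low oxygen dark culture, in whose channel purF, purD, cheB, carB, thrS, gyrA, map and infB were below background on both arrays. Without it and the oxygen term purF had 0.13, sucD 0.20, purD 0.024, lpdA 0.11, cheB 0.061, dpsA 0.073, glnA 0.015, psmA 0.068 and ppsA 0.0074, while nuoL had 0.20. On the lower side carB had −0.0066, thrS −0.12, aspS −0.14, pyrB −0.10, gyrA −0.11, map −0.15 and infB −0.014. The sign of infB turned without low oxygen dark replicate 2 (0.034), and nuoL had 0.035 without high oxygen dark replicate 1. The other succinyl-CoA synthetase subunit gene, sucC, had a light difference of 0.071 in the main fit, against 0.52 for sucD. In all, 18 of the 82 measured named genes kept 1 sign, against 12.1 expected if the differences in high and in low oxygen were unrelated. Limited to measured positions, the fit called 6, 1 higher and 5 lower, and the higher one was purF (adjusted p = 0.01003; over the alternatives for purF this ranged from 0.000304 to 0.999). Leaving out low oxygen light replicate 1 gave 15 calls and low oxygen dark replicate 1 gave 9. Leaving out a culture together with the oxygen term gave 355 calls for the high oxygen dark and 115 for the low oxygen dark culture; light is then partly confounded with oxygen, and the oxygen term alone dropped gave 0.

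Of the light-related genes themselves, sop1 had 0.27, htr2 −0.16, sop2, the gene of sensory rhodopsin II, −0.11 and htr1 0.028 in light over dark. The phototrophy list had a median of −0.043, a mean of 0.035 and a camera direction of lower (adjusted p = 0.861). Chemotaxis genes had a median of 0.12 with 9 of 11 higher (camera adjusted p = 0.205), with medians of 0.25 in low and 0.044 in high oxygen. The cobalamin list had a median of −0.23 with 3 of 4 lower, among them cbiT (−0.26) and cbiG (−0.23), and did not pass (camera adjusted p = 0.146). Its median was −0.40 in low oxygen, where the low oxygen dark culture enters, and −0.014 in high oxygen. The citric acid cycle list had a median of −0.041 and a mean of 0.045, with a camera direction of lower (adjusted p = 0.861), and its members ran from sucD at 0.52 to icd, isocitrate dehydrogenase, at −0.21. In arginine fermentation arcA had −0.18 and arcC −0.013, a value that turned sign in 12 of 29 alternatives.

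The oxygen by light difference asks whether the oxygen difference depends on light. With 1 culture per condition it has no test across cultures and is given as values. The lowest values were −1.04 for purF and −1.02 for purL, followed by argH (−0.75), glyA (−0.74) and purD (−0.53). By the log2 ratios the oxygen difference of the 3 purine genes was larger in the dark. Only bounds hold against the low oxygen dark culture, so this order is not settled. Of these 5 genes, glyA alone was above background in the culture channel on the low oxygen dark arrays. The highest were phnE (0.45), a phosphonate transport gene, cbiQ (0.44), a cobalt transport gene, fer2 (0.36), a ferredoxin, pyrB (0.35) and htr2 (0.35). A limma fit to the 8 arrays, which covers hybridisation error only, called 0 positions, with 111 at an unadjusted p under 0.05. Over measured positions the values of the dye orientations correlated at r = 0.0076, so most of the spread of this difference (SD 0.359) was not shared by a culture's arrays.

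The oxygen difference in light and the oxygen difference in the dark share no culture. Across the 981 measured positions, which are not independent replicates, they correlated at Pearson r = 0.191 and Spearman rho = 0.131, and over all 2688 positions at r = 0.0042. Within single dye orientations r was −0.0061 in Alexa 532 and 0.0328 in Alexa 647. The light differences in high and in low oxygen correlated at r = 0.186 and rho = 0.157 over measured positions and r = 0.161 over all, and within the orientations at r = −0.0237 and 0.0942. Differences that involve the low oxygen dark culture were wider: the SD was 0.359 for oxygen in the dark and 0.358 for light in low oxygen, against 0.138 for oxygen in light and 0.139 for light in high oxygen.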

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

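All tests weighed in this part were chosen after the results were seen except the test of signal loss in the purine genes and the test of a dye effect of each gene.

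In the low oxygen dark culture the log2 ratios were wider than in any other, with SDs of 0.597 and 0.445 on its arrays. Spot-level noise alone is argued against for replicate 1, where the SD shared by the opposite sides of the slide was 2.70 times the highest of the other 6 arrays (95% bootstrap interval 2.40 to 3.05), and remains open for replicate 2 (1.58, interval 1.35 to 1.81). A difference in the culture's own RNA predicts that its opposite-dye arrays share the deviation; their shared SD was 0.209 against 0.126 in the highest other culture. This exceeds the others but is a smaller part of the arrays' spread than that explanation needs, so RNA of the culture and labelling or hybridisation of each array cannot be told apart. With 1 culture on weakly stained arrays, a true response to low oxygen in the dark stays open and untested.

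Purine synthesis genes read low in that culture, and their calls in the oxygen and light comparisons rest on it. None of the 6 genes was above background in either channel on either of its arrays, so list medians there decide neither on uneven print blocks nor on dye bias, and both stay open. Loess within each block gave a list median of −0.41 in that culture against −0.38 with global loess, and the higher of its opposite-dye arrays had −0.27, against 0.074 on the lowest of the other 6 arrays. A general loss of signal among dim genes remains open too: among random lists from the 51 measured named genes below background in that culture's channel, the purine median lay at the 4.26 percentile on 1 array and at 14.9 on the other. A lower level of purine transcripts in low oxygen and darkness stays open as an untested hypothesis.

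Arrays of the same dye orientation but different cultures correlated at a median r of 0.561 over measured positions in 12 pairs. Arrays of the same culture in opposite dyes had a median r of 0.138 over 4 pairs, and arrays of different cultures in opposite dyes also 0.138 over 12. Uneven print blocks are argued against as the whole cause. With loess within each block the medians were 0.522, 0.410 and 0.348. The same-orientation median stayed above the highest same-culture pair (0.454), though the lowest same-orientation pair had 0.360. These medians lie much closer together than with global loess, which the main fit uses. Print blocks therefore stay open as a part of the cause. The dye difference of each position in the high oxygen arrays correlated at r = 0.759 with that in the low oxygen light arrays, as a dye effect of each gene predicts. This r follows largely from the array correlations above. It was computed with global loess, so an effect of the place on the slide could give it too. A dye effect of each gene stays a candidate that this test cannot single out. No biological explanation was tested, because both orientations hold the same cultures.

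Among 9 genes tested, the low oxygen dark culture stood far from the other 3 for argH (log2 ratio −0.79, gap over range 0.836) and for glnA (−0.43, gap over range 0.904), above Dixon's 95% critical value for 4 cultures; chance gives this in about 1 of 20 groups. For argH the culture channel was above background on neither array there (−1.25 and −0.33), so its distance is not a measured level. For glnA the Alexa 532 array (−0.17) lay within the range of the other 6 arrays (−0.22 to −0.070), and the distance comes from the weakest array (−0.69). The same culture enters every opposite pair below.

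In some genes both arrays of a comparison moved one way in 1 background and the opposite way in the other; 35 genes and 70 comparisons were looked at, and with 1 culture per condition none of these differences could be tested across cultures. The fit of the 8 arrays, which covers hybridisation error only, called none as a difference between backgrounds (lowest adjusted p of all positions 0.949, with 111 at an unadjusted p under 0.05). The oxygen difference in light and in the dark was −0.15 and 0.59 for glyA, −0.075 and 0.68 for argH, 0.091 and −0.11 for nuoL, 0.078 and −0.27 for pyrB, 0.12 and −0.33 for phnE, and 0.10 and −0.24 for htr2. The light difference in high and in low oxygen was −0.11 and 0.64 for argH, −0.12 and 0.35 for pheA, −0.036 and 0.40 for purM, and 0.017 and −0.33 for htr2.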

How the results depend on the processing

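The tests of the spot statistic, low-gain scan, saturated spots, and most list and pyrF settings were chosen after the data were seen. Over 73 results, 1346 of 1904 alternative values kept their direction and side of the threshold, or moved by less than the spread between arrays; 102 lost a call, 34 gained 1, 421 counts or values not past the threshold moved and 1 reversed. The first of these counts is partly built in. The spread used is that between the 2 dye orientations, and the main value is their mean. For a named gene not called, each single orientation therefore lies within it by construction. In light, arcC was counted as kept in 29 of 29 alternatives although its sign turned in 12. Named genes kept their sign in 1535 of 1581 values, but much of this is built in too. Settings that change only the filter, the variance model or the covariates of all 4 cultures leave these log2 values as they are. Most of the genes were also picked for 1 sign in every separate comparison. The sign turned for arcC in 12 values in light, 4 in oxygen and 1 against the reference, and for pyrF in 10 in oxygen and 4 in light. It turned in 2 values each of bat and thrS in oxygen and of carB, infB and map in light, and in 1 each of carB and pyrI in oxygen, ppsA and psmA in light, and arcA against the reference. Among these, median centring turned infB and ppsA; the authors' values pyrI, thrS, map, and carB in light; and the low-gain scan thrS, map, and carB in both. Causes were not tested unless stated. The reversed value is the pyrimidine oxygen median with the authors' values, 0.00033.

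The 64 calls against the reference became 220 with a variance trend and 210 with the culture as a random block (correlation within a culture −0.304), 197 with the low-gain scan, 165 and 35 when only positions above background on at least 4 or on all 8 arrays were tested, 109 with median centring, 37 without saturated spots, 23 with offset 0, 23 from the Alexa 532 orientation, 14 without covariates, 6 with mean foreground and median background, 3 (1 higher, 2 lower) with scaling between arrays and 0 from the Alexa 647 orientation in limma (451 at an unadjusted p under 0.05). Leaving out arrays, or cultures together with the covariates, gave 0 to 183. Shared calls were 64 of the 220 and 33 of the 165. The negative correlation of −0.304 makes the blocked fit count a culture's 2 arrays as more than 2 independent ones. Its 210 calls, and the glyA, panB and pheA calls it gained, are therefore no stronger evidence.

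Oxygen calls were 17 and 4, and light calls 6 and 1, with the filters at 4 and 8 arrays, where fewer positions are tested and the pooled spread differs. Fewer tests alone do not explain them: for purF in oxygen the limma adjusted p of 0.0177 lies below the main unadjusted p of 0.0225. The lowest limma adjusted p against the reference was 2.7e-76 with the filter at 4 arrays, against 3.2e-05 in the main fit. Such values rest on the pooled spread, as does the 7.6e-10 of pyrF without high oxygen dark replicate 2. Median centring gave 2 oxygen calls and 1 light call. Leave-outs gave 0 to 8 for oxygen and 0 to 355 for light. Fits without a culture also drop the other factor and so differ from the main model in more than the culture; that factor alone dropped gave 0 and 0. A lone culture is there assumed to vary like the others.

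The pyrF value lost its call with scaling between arrays (−0.86, adjusted p = 0.0847), in the Alexa 647 orientation (−0.94), with the low-gain scan (−0.0727) and without any culture, where values ran from −0.92 to −0.78; over the alternatives its adjusted p ranged from 7.6e-10 to 0.540. Of 5 list calls, 4 were kept without covariates, 3 with median centring, with print-block loess and with mean foreground and background, 2 with mean foreground and median background and in the Alexa 532 orientation, 1 with offset 0 and with scaling, and 0 with the authors' values, in the Alexa 647 orientation and without saturated spots. With an estimated correlation 0 were kept too, but that estimate rests on 1 residual degree of freedom and decides nothing. Leave-outs gave 1 to 4 calls, of which 0 to 4 were among the 5. With no background subtraction and with the low-gain scan 1 further call was made, beside 4 and 3 of the 5.

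The correlation of the oxygen differences (0.191) was 0.288 with the authors' values, 0.243 without background subtraction, 0.152 with mean foreground and background, 0.150 for positions above background on all 8 arrays, 0.145 with the low-gain scan, 0.0328 in Alexa 647 and −0.0061 in Alexa 532. That of the light differences (0.186) was 0.0942 in Alexa 647, 0.0636 with the low-gain scan and −0.0237 in Alexa 532. The SD of the oxygen by light difference was 0.571 in Alexa 532. With no quality flags found, the planned run that keeps low-quality spots was not made, and camera was not run on positions above background on all 8 arrays. No paired analysis was possible because the replicate number marks the dye orientation and each condition has 1 culture. Signal limits the low oxygen dark culture most, at 0.967 to 1.94 times background.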

Other observations

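The gene groups described here and their medians were chosen after the gene names were seen, and the test of neighbouring genes was planned before its result was seen.

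Aminoacyl-tRNA synthetase genes, 12 of them with 7 measured, had medians of −0.040 against the reference, −0.030 for oxygen and −0.024 for light. Their single values lay on both sides of 0. They ran from −0.25 to 0.13 against the reference, from −0.36 to 0.13 for oxygen and from −0.35 to 0.16 for light. The 6 histidine synthesis genes, 2 of them measured, had a median of −0.063 against the reference with 6 of 6 lower, at the 49.1 percentile of random groups matched on brightness, since the median of all named genes was −0.071. They had medians of 0.012 for oxygen and −0.062 for light. The 3 thiamine synthesis genes, 2 of them measured, had a median of −0.15, at the 16.2 percentile. Of the 3 glutamate dehydrogenase genes, which link glutamate to the citric acid cycle, the 2 measured ones lay on opposite sides of the reference, gdhA1 at 0.27 and gdhB at −0.054. The other, gdhA2, had 0.17 and was above background on only 3 arrays. None of the 3 histidine breakdown genes was measured.

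Neighbouring genes in the genome of strain 91-R6 might share a difference if they are transcribed together. The pairs include cheA with cheB, carB with carA, and sucC with sucD, whose oxygen values were 0.023 and 0.42. Over 12 neighbouring pairs of measured genes, none printed in the same block, the mean absolute gap in log2 was 0.135 against the reference, 0.143 for oxygen and 0.154 for light. These gaps lay at the 23.5, 6.06 and 5.89 percentile of random pairs. The bound set beforehand was the 5th percentile. All of these percentiles lay above it, on the side set beforehand for no shared difference. With only 12 pairs, and with the oxygen and light values close to the bound, this does not exclude a shared difference. Whether neighbours share differences on these arrays thus cannot be told apart from chance.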
